A study of Mus musculus with 52 samples.

How the data were processed

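Single daughter cells of mouse burst-forming unit-erythroid (BFU-E) founders were profiled by RNA sequencing of polyadenylated transcripts. BFU-E cells are early progenitors already committed to the red cell lineage. Per the labels' protocols, they came from fetal liver of C57/Bl6J embryos at day 14.5, were depleted of cells carrying markers of mature blood lineages, stem cells, granulocytes and megakaryocytes, and were then sorted with antibodies against Kit, the transferrin receptor and CD24. Founders were placed 1 per well with 100 nM dexamethasone, a synthetic glucocorticoid, or without it. Wells in which the founder had divided once after 16 hours gave 2 daughter cells, which were sequenced separately. The 52 libraries make up 13 untreated and 13 dexamethasone pairs. How the libraries were prepared is not given in the sources used here.

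The authors deposited raw counts of reads per gene, 1 whole-number table per treatment, without normalization. Per the submitters' processing notes the tools were STAR 2.4 and featureCounts and the genome build was GRCm38. The settings for strand and for reads shared between genes are not given in the sources used here, so genes with near-identical copies, such as Hba-a1 and Hba-a2 or the ribosomal protein genes with their pseudogenes, carry an uncertain split of reads, and overlapping or antisense genes may share reads. Both tables held the same 49466 genes. Each column name matched the description of 1 sample and 0 columns were left unused. No molecular identifiers are mentioned, so read counts are not counts of molecules, and no library was identical to another. Gene locations were taken from GENCODE mouse release M21, which uses GRCm38, by Ensembl identifier. All 201 identifiers looked up were found there.

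The pair, that is the founder cell with its own well, was the replicate, and the counts of its 2 cells were summed for comparisons between treatments. The labels name no animal, so p-values measure the spread between founder cells and wells, which may share an embryo or a litter. All libraries came from 1 sequencing lane. Plate positions in the labels place untreated pairs in library plate columns 1, 2, 5 and 6 and dexamethasone pairs in columns 3, 4, 6 and 7. Columns 1 to 4 and 5 to 7 were treated as technical sets that each hold both treatments. Of the single columns only column 6 holds both. Neither a split by these sets nor a covariate for them can therefore separate dexamethasone from effects of single columns.

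Total counts per library ranged from 0 to 5606500. Exactly 4 libraries held fewer than 100000 counts, and all 4 were untreated. They belong to pairs 4, 7 and 12. They stayed in the planned tests, except that the empty library could enter no test of single cells, which left 12 untreated pairs in comparisons of 2 daughters. Pair means of log2(CPM + 1) and of scores rest on 1 cell in untreated pair 4. The comparisons of treatments and of daughters were also computed without the 3 pairs, a choice made after the depths were seen.

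Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the treatment with its minimum count of 10 and minimum total of 15, counts were scaled by TMM, and glmQLFit and glmQLFTest gave quasi-likelihood p-values with Benjamini-Hochberg adjustment over all genes tested. A standard error beside a log2 fold change is that change divided by the square root of the F statistic. Changes with an adjusted p under 0.05 were called. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 for lists with at least 3 tested genes, with an estimated correlation and with fry from limma 3.58.1 beside it. The 29 lists and the markers of other cell types were fixed before the data were examined, as were the other settings to be tried and the rule for naming genes.

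Values of single cells were log2(CPM + 1), where CPM scales the counts of a gene to the total of its library. Tests of single cells used the 8080 genes with at least 5 counts in at least 10 of the 52 libraries. The similarity of daughters was the Pearson correlation across these genes, compared with 100000 random re-pairings of cells within a treatment. Comparisons of single values between treatments used two-sided permutation tests with 100000 resamples, or every assignment where a group had fewer than 10 pairs, and 95% bootstrap intervals from 10000 resamples of pairs. The erythroid progression score of a cell was the mean of the late erythroid list minus the mean of the early progenitor list. Genes shared by daughters were tested in edgeR with 1 term per pair within each treatment. The cell number within a pair, which goes with the plate row, served as a negative control with the pair as a block.

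For the dexamethasone comparison the rule named the 5 genes with the smallest p in each direction if fewer than 5 were called, leaving out predicted genes without a name, up to 4 genes of each list, and 15 genes always. List genes are named here for 7 lists described in detail (glucocorticoid response, early progenitor, late erythroid, heme synthesis, G1/S, G2/M and glycolysis), a choice made after the values were seen. For genes shared by daughters it named the 12 with the smallest p. Some genes that the rule names are not reported here. Of the 15 genes, 4 were left out by the expression filter (Fkbp5, Tsc22d3, Per1 and Cdkn1c). A permutation test of the 15 genes on the pair mean of log2(CPM + 1) was therefore added after the data had been seen, with adjustment over the 15 alone. A library of at least 100000 counts was called myeloid-like when its granulocyte and monocyte marker score lay above its late erythroid score. This rule was also set after the data had been seen.

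The edgeR steps were tested on simulated counts with 200 changed genes. For the dexamethasone comparison, run on 6429 genes, 0% of the genes changed 2-fold were recovered, 20% of those changed 4-fold and 52% of those changed 8-fold. For genes shared by daughters, run on 8080 genes, 20.5% of the genes with a simulated founder effect (SD 2 on the log2 scale) were recovered with 0 false calls. Random re-pairings of the real cells gave 60 and 74 calls, so the 0 does not carry over to the real data. The alternatives covered RLE, TMMwsp and no scaling, other expression filters, DESeq2 1.42.0, limma on log2(CPM + 1), single cells of a pair, plate position and number of detected genes as covariates, left-out pairs, other pseudocounts, rank correlation, and counts thinned to 210383 per library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.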

Results

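The data were single-cell transcriptomes of daughters of sorted mouse BFU-E founders that had divided once in culture, from 13 untreated pairs and 13 pairs kept with 100 nM dexamethasone for 16 hours. Median library totals were 2644093 counts without and 2577701 counts with dexamethasone. In untreated pair 4 the daughters held 13575 and 0 counts, in pair 7 cell 1 held 5733 and in pair 12 cell 2 held 11791. The other 48 libraries held at least 210383 counts and detected 3886 to 9473 genes each. Without those 3 pairs the log2 total of a pair was 22.24 ± 0.85 (SD, n = 10) untreated and 22.23 ± 0.63 (SD, n = 13) with dexamethasone, a difference within the spread between pairs (two-sided permutation p = 0.964).

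The first comparison asked which transcripts dexamethasone changed in the daughters. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, was higher with dexamethasone, at 4.25 ± 2.38 against 0.61 ± 1.41 log2(CPM + 1) per pair (SD, n = 13 pairs each). The difference was 3.64 with a 95% bootstrap interval of 2.13 to 5.03. Tsc22d3 (ENSMUSG00000031431) lies on chromosome X from 140539528 to 140600659 on the minus strand of GRCm38. It reached 10 CPM in 16 of 26 dexamethasone libraries and in 2 of 22 untreated libraries with at least 100000 counts, spread over 10 and 2 pairs. Its two-sided permutation p was 0.00015, or 0.00225 adjusted over the list alone, and it was the 1 gene of the 15 fixed genes to pass. That test was added after the expression filter had left Tsc22d3 out and after its values had been seen. In a wider filter edgeR gave a log2 fold change of 2.32 on summed counts with an adjusted p of 1.00 over all genes. The difference was 4.53 in plate columns 1 to 4 (n = 8 pairs each, exact permutation p = 0.000311) and 2.22 in columns 5 to 7 (n = 5 pairs each, exact permutation p = 0.127).

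The other fixed glucocorticoid targets did not pass. Fkbp5, a co-chaperone of the glucocorticoid receptor (chromosome 17 from 28399094 to 28517527), was at 2.36 ± 2.23 with and 0.86 ± 1.26 log2(CPM + 1) without dexamethasone (SD, n = 13 pairs each, permutation p = 0.0437, 0.219 adjusted over the list alone). Per1, a clock gene, was at 2.34 ± 2.33 and 0.88 ± 1.33 (permutation p = 0.0593, 0.222 adjusted over the list alone). In plate columns 1 to 4 the differences were 2.42 for Fkbp5 and 2.67 for Per1 (n = 8 pairs each), against 0.026 and -0.47 in columns 5 to 7 (n = 5 pairs each). A test of that contrast without the 3 shallow pairs, where columns 5 to 7 gave -0.26 and -0.44, had adjusted permutation p = 0.288 for each. Cdkn1c, a cell cycle inhibitor, reached 10 CPM in 0 untreated and 2 dexamethasone pairs. Of the 11 tested members of the glucocorticoid response list, 6 had a positive and 5 a negative log2 fold change, and camera gave an adjusted p of 0.472. The list holds 36 genes, and the expression filter kept the rest out of that test, as it did Tsc22d3, Fkbp5 and Per1. The metallothioneins Mt1 and Mt2, which bind metal ions, were at log2 fold changes of 0.73 ± 0.40 (SE) and 1.85 ± 1.04 (SE), Klf9, a glucocorticoid-inducible transcription factor, was at 1.27 ± 1.23 (SE) and Angptl4, an inhibitor of lipoprotein lipase, at -1.14 ± 1.25 (SE). None of the 4 was called by edgeR (adjusted p = 1.00).

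**Figure D1:**
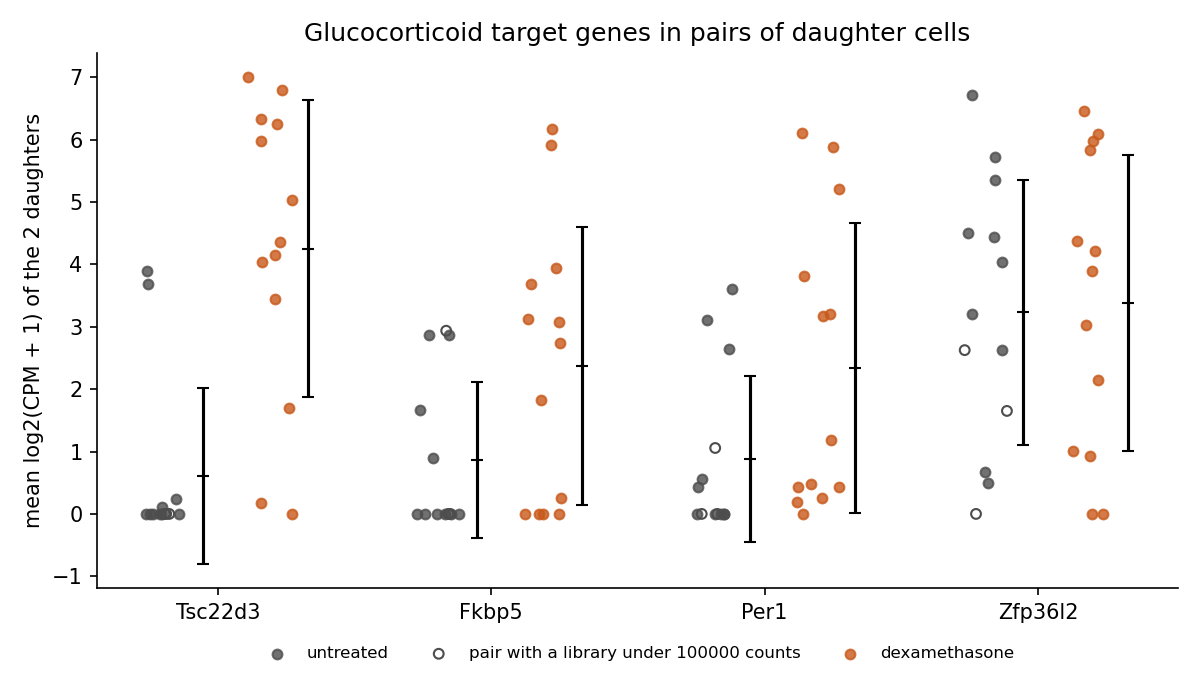
Mean log2(CPM + 1) of the 2 daughters, or of the 1 non-empty daughter in untreated pair 4, for 4 glucocorticoid target genes, with each point a pair, open points pairs with a library under 100000 counts, and bars mean ± SD over 13 pairs. Tsc22d3 averages 4.25 with and 0.61 without dexamethasone.

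Across all genes 0 of 6429 passed in edgeR's quasi-likelihood test, where 102 had an unadjusted p under 0.05. Limma-trend called 0 (251 with an unadjusted p under 0.05) and DESeq2 called 2, Mpo and Tmsb4x (140 with an unadjusted p under 0.05), named here after their values were seen. With the smallest p among genes higher with dexamethasone were Polr2d, a subunit of RNA polymerase II (log2 fold change 1.24 ± 0.34, SE), Ldha, lactate dehydrogenase A (0.49 ± 0.14), the blood group gene Kel (5.03 ± 1.52), the mitochondrial chaperone gene Trap1 (1.11 ± 0.34) and the adaptor gene Samsn1 (1.13 ± 0.35). Among genes lower with dexamethasone they included Dut, which encodes dUTPase (-4.16 ± 0.93), Mthfd2 of mitochondrial folate metabolism (-2.29 ± 0.75), M6pr, the cation-dependent mannose 6-phosphate receptor (-0.82 ± 0.29), and the kinase gene Map2k2 (-2.16 ± 0.76). The adjusted p was 0.710 for Dut and 1.00 for the others named. Without untreated pair 4, whose 2 libraries were almost empty, Dut was at -0.52, Mthfd2 at 0.0059 and Map2k2 at -0.08, and without dexamethasone pair 10 Kel was at -1.46.

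Genes of glycolysis were on balance higher and cell cycle genes lower with dexamethasone by camera at its preset correlation. On the mean log2(CPM + 1) of a list per pair, 0 of 21 lists differed between treatments by permutation (smallest adjusted p = 0.854). Glycolysis differed by 0.25 there (permutation p = 0.378), G1/S by -0.45 (0.147) and G2/M by -0.32 (0.587). In the glycolysis list 12 of 16 genes had a positive log2 fold change (median 0.27, adjusted p = 0.00427, 0.171 with an estimated correlation). Its examples were Ldha (chromosome 7 from 46841475 to 46855627; 2909 ± 537 CPM with and 2068 ± 472 CPM without dexamethasone, SD, n = 13 pairs each), Aldoa, fructose-bisphosphate aldolase A (0.53 ± 0.19, SE), Tpi1, triosephosphate isomerase (0.53 ± 0.21, SE), and Gapdh, glyceraldehyde-3-phosphate dehydrogenase (0.31 ± 0.24, SE). On the mean log2(CPM + 1) of the daughters, without the 3 shallow pairs and with the plate columns as covariate, 9 of the 16 were positive by limma. Of the G1/S genes 27 of 38 were negative (median -0.18, adjusted p = 0.00427, 0.302 with an estimated correlation), among them Rrm2, a ribonucleotide reductase subunit (-0.60 ± 0.32, SE), the cyclin gene Ccne1 (-1.39 ± 0.85, SE), Wdr76 (-0.85 ± 0.67, SE) and the replication fork gene Tipin (-0.36 ± 0.28, SE). Of the G2/M genes 29 of 40 were negative (median -0.24, adjusted p = 0.00660, 0.637 with an estimated correlation), with the spindle genes Tpx2 at -2.17 ± 0.96 (SE), Ckap2 at -1.16 ± 0.83 (SE) and Tacc3 at -0.53 ± 0.40 (SE) and Mki67, a proliferation marker, at -0.86 ± 0.56 (SE). None of these genes passed alone in edgeR, and Tpx2 was at 0.28 without untreated pair 4. Without the 3 pairs with a shallow library, 0 of the lists passed, at adjusted p = 0.0868 for glycolysis, 0.0545 for G1/S and 0.114 for G2/M. With the plate columns as covariate in that fit glycolysis (higher), G1/S and mitochondrially encoded genes (both lower) passed (adjusted p = 0.0269 each by camera; 0.365, 0.620 and 0.752 with an estimated correlation). With all pairs fry called glycolysis alone (adjusted p = 0.0461), and without the shallow pairs it gave 0.356 for that list. The G2/M list turned to the opposite direction when pairs with a myeloid-like daughter were left out as well (adjusted p = 0.688 by camera).

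Late erythroid genes gave a mixed picture. The list was called lower by camera (20 of 35 genes negative, median -0.32, adjusted p = 0.0194, 0.638 with an estimated correlation). Its mean log2 fold change was 0.02, of the opposite sign. That mean includes Kel at 5.03, which was at -1.46 without dexamethasone pair 10. By limma without the 3 shallow pairs, with the plate columns as covariate, 28 of the 35 genes were negative. The median over all 6429 genes in that fit was -0.17, so genes in general leaned the same way. The camera call was lost without any 1 of 9 pairs (adjusted p up to 0.291). Kel, Nfe2, an erythroid transcription factor gene (1.36 ± 0.81, SE), and Car1, carbonic anhydrase 1 (1.39 ± 1.08, SE), were positive, and Tfrc, the transferrin receptor gene, was at -0.77 ± 0.62 (SE). All 8 tested heme synthesis genes were negative, with Cpox at -1.005 ± 0.86, Alas1 at -1.05 ± 1.30, Fech at -0.40 ± 0.52 and Ppox at -0.62 ± 0.87 (SE), and the list missed the threshold (adjusted p = 0.0622 by camera), which it passed with RLE scaling (0.0488) and with the filter of 10 counts in 5 pairs (0.0201). In the same limma fit without shallow pairs and with the plate columns as covariate, 2 of the 8 were positive. By limma with all pairs Alas1 was at 1.01. The erythroid regulators Gata1 (0.33 ± 0.71), Klf1 (0.14 ± 0.73) and Epor, the erythropoietin receptor (-0.32 ± 0.85), the adult globin genes Hba-a1 (0.58 ± 0.96) and Hbb-bt (-1.01 ± 1.07), and the progenitor genes Kit (0.36 ± 0.72), Gata2 (0.20 ± 1.25), Zfp36l2 (0.43 ± 0.94), Myc (0.83 ± 0.55), Myb (1.71 ± 0.97), Etv6 (2.15 ± 1.26) and Ccnd2 (0.52 ± 0.43) lay within 2 SE of 0. On the mean log2(CPM + 1) of the daughters Myc was at 9.10 ± 1.14 with and 7.40 ± 2.70 without dexamethasone (SD, n = 13 pairs each, permutation p = 0.042, 0.219 adjusted over the list alone). Without the shallow pairs its permutation p was 0.0247, or 0.129 adjusted over the list alone. Without myeloid-like pairs as well, the Myc permutation p was 0.134, or 0.504 adjusted over the list alone. With only the shallow pairs left out, Tfrc was at 5.91 ± 2.88 with (SD, n = 13) and 8.16 ± 1.06 without dexamethasone (SD, n = 10). Its permutation p was 0.0259 (0.129 adjusted over the list alone), against 0.145 with all pairs and 0.203 without myeloid-like pairs as well. The glucocorticoid receptor gene Nr3c1 was at -0.18 ± 1.14 (SE). Of the other lists tested none passed. Adult globin and ribosomal protein genes and hypoxia targets came to adjusted p = 0.0719 each, cholesterol synthesis and ATF4 targets to 0.110 each, early progenitor genes (15 of 21 positive) to 0.199, mitochondrially encoded genes to 0.325, CDK inhibitors and cyclins to 0.472, ribosome biogenesis to 0.619, STAT5 and p53 targets to 0.752 each and immediate early genes to 0.814. NF-kB and interferon genes kept 2 tested members each and embryonic globin genes 0.

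**Figure D2:**
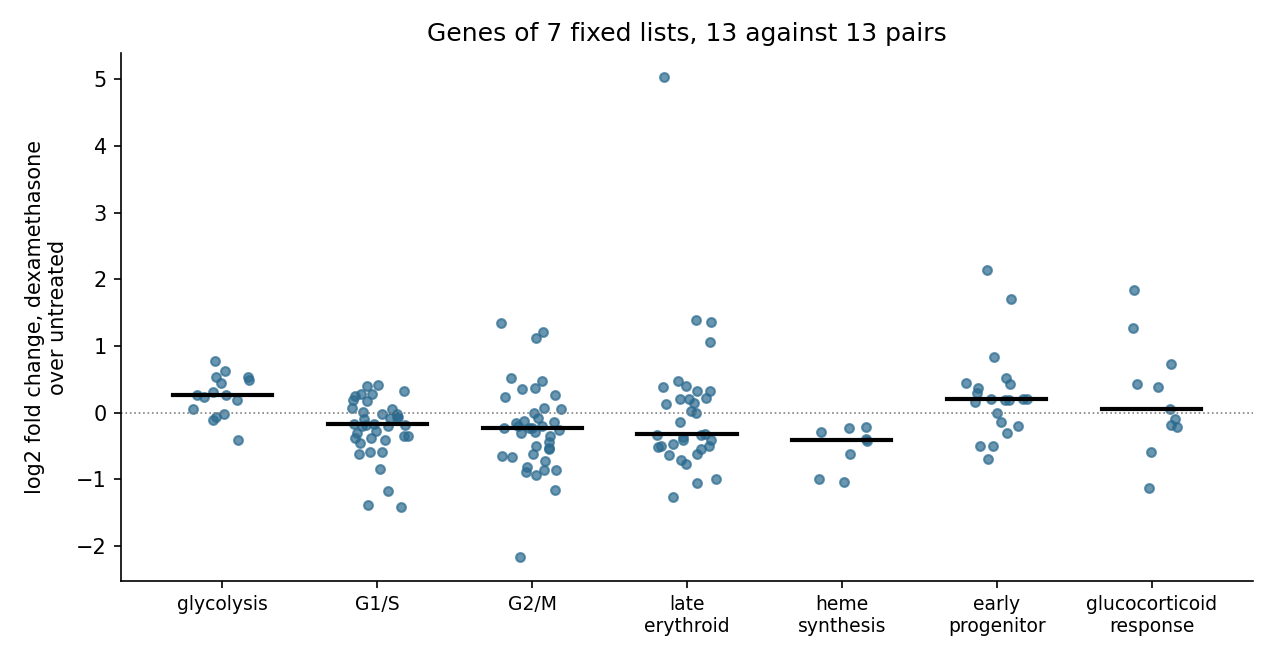
Log2 fold changes, dexamethasone over untreated, of the tested genes in 7 fixed lists from the edgeR test of 13 against 13 pairs. Each point is a gene and each bar the median, which is 0.27 for glycolysis and -0.18 for G1/S genes; no single gene passed the threshold.

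The second comparison asked whether daughters of 1 founder were more alike than cells of different founders. They were, in both treatments. The correlation between daughters across 8080 genes averaged 0.521 ± 0.066 in untreated pairs (SD, n = 12) against 0.466 for re-paired cells, and 0.520 ± 0.059 (SD, n = 13) against 0.461 with dexamethasone. Each two-sided permutation p was 1e-05, the smallest that 100000 re-pairings can give. Re-pairing within a plate column gave expected correlations of 0.493 and 0.486 and permutation p = 5e-05 and 2e-05. Daughters lay above their own mean with other cells in 10 of 12 untreated and 12 of 13 dexamethasone pairs.

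**Figure D3:**
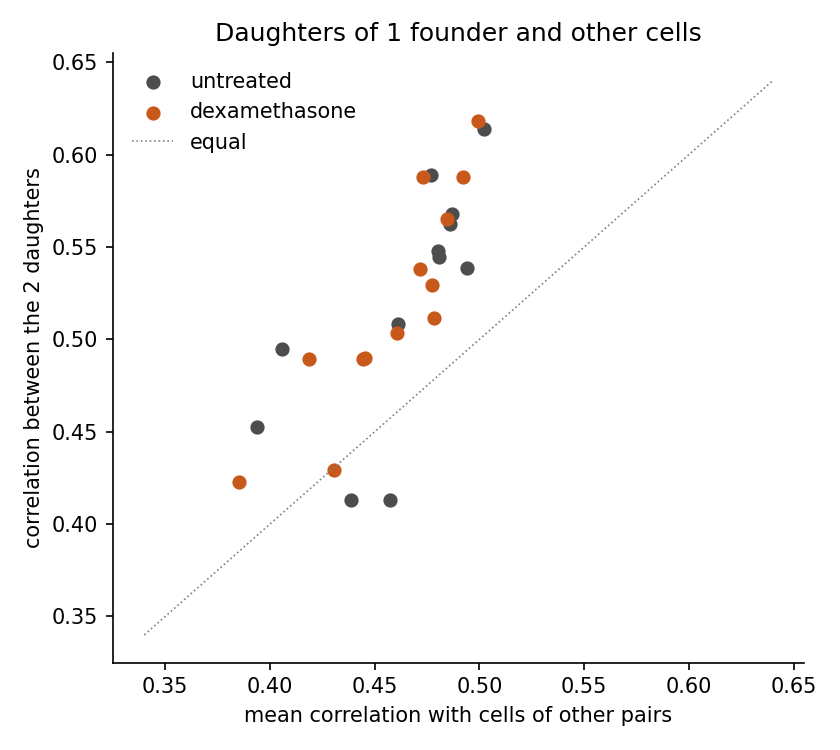
Correlation between the 2 daughters of a founder against their mean correlation with cells of other pairs of the same treatment, both of log2(CPM + 1) across 8080 genes. Each point is a pair; 10 of 12 untreated and 12 of 13 dexamethasone pairs lie above the dotted line of equality.

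Dexamethasone did not measurably change how far daughters diverged. The distance, 1 minus the correlation, was 0.480 ± 0.059 (SD, n = 13) with and 0.480 ± 0.066 (SD, n = 12) without dexamethasone, a difference of 0.0003 with a 95% bootstrap interval of -0.048 to 0.047 (permutation p = 0.991). Without the 3 pairs with a shallow library the difference was 0.022 (permutation p = 0.349).

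Genes that daughters of 1 founder shared, and that differed between founders, included granulocyte and erythroid genes. The edgeR test called 262 of 8080 genes (1565 with an unadjusted p under 0.05; limma called 516, 136 of them shared). The 12 with the smallest p included Prtn3 and Mpo, which encode granule proteins of neutrophils, Dut, Cd24a, Emb, Hba-a1, Klf1, Plac8, Hmgn2, Cfl1 and Lmna. Mpo (chromosome 11 from 87793581 to 87804413) differed by 1.26 ± 1.93 between daughters (SD, n = 23 pairs) and by 5.49 between cells of different founders on the log2(CPM + 1) scale. For Klf1 the values were 0.93 ± 1.20 and 3.51, for Hba-a1 0.84 ± 0.74 and 3.99, and for Cd24a, whose product was used in the sort, 1.07 ± 1.34 and 4.20. Without the 3 shallow pairs Dut was not called (adjusted p = 0.635 in edgeR). In the 23 other pairs it differed by 1.00 ± 0.93 between daughters (SD) and by 1.15 between cells of different founders. Its call with all pairs thus rests on the shallow pairs, and untreated pair 4 among them has no second daughter with counts. It does not show that daughters share Dut. Without the myeloid-like pairs as well, Mpo, Prtn3 and Klf1 were not called in edgeR (adjusted p = 0.159, 0.274 and 0.288), although limma called Mpo at 0.00775. Emb, Plac8 and Cfl1 were called there by neither edgeR (0.2985, 0.553 and 0.643) nor limma (0.472, 0.423 and 0.628). Hba-a1, Cd24a, Hmgn2 and Lmna stayed called in edgeR (0.000401, 0.00181, 0.0274 and 0.00762). With all pairs limma did not call Cfl1 (adjusted p = 0.5255).

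By list, 15 of 39 late erythroid genes were shared by daughters (adjusted Fisher's exact p = 8.14e-12), with Gata1 and Rhag among them. The other lists past the threshold were mitochondrially encoded genes (7 of 8, adjusted p = 2.85e-09), ribosomal protein genes (17 of 84, adjusted p = 7.36e-09), granulocyte and monocyte markers (5 of 5, adjusted p = 1.81e-07), adult globins (2 of 4, adjusted p = 0.0211), hypoxia targets (3 of 12, adjusted p = 0.0211) and megakaryocyte markers (2 of 5, adjusted p = 0.0295), all by Fisher's exact test. Fisher's test counts genes as independent, so these p-values do not measure the spread between founders. The filter of 5 counts in 10 libraries kept 5 of the 15 granulocyte and monocyte markers. The 5 pairs with 2 myeloid-like daughters make up 10 libraries, so markers can enter through those pairs alone. The count of 5 of 5 is therefore no separate support for sharing. Genes within a list can vary together: where camera tested these lists for dexamethasone, the estimated correlation ran from 0.13 (hypoxia targets) to 0.73 (adult globins). Without the 3 shallow pairs and the 6 pairs with a myeloid-like cell, 34 genes were called by edgeR and 227 by limma. In edgeR 3 of 8 mitochondrially encoded genes, 2 of 4 adult globins and 3 of 39 late erythroid genes (Car2, Cd24a and Ermap) passed, with Ftl1, the ferritin light chain gene, at the smallest adjusted p in edgeR (2.22e-07), and 0 ribosomal protein and 0 myeloid genes did. Within a plate column, with all pairs, 66 genes were called, and the 3 mitochondrially encoded genes were not among them (mt-Co1, mt-Nd1 and mt-Nd2, adjusted p = 0.493, 0.530 and 0.331 in edgeR). In 2 random re-pairings within a treatment, without the 3 shallow pairs, edgeR still called 60 and 74 genes, against 270 with the real pairs. Part of those 270 calls can therefore arise without shared founders. For the 262 calls with all pairs no re-pairing was run in edgeR.

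Markers of other lineages were looked for in each of the 48 deeper libraries. In 15 of them at least 3 granulocyte and monocyte markers reached 10 CPM, and in 19 at least 3 megakaryocyte markers did. For stem cell markers the number was 4, and for mast cell, lymphoid, macrophage, hepatocyte and endothelial markers 0. By the score rule both daughters were myeloid-like in 5 of 23 pairs, 2 untreated and 3 with dexamethasone, and 1 daughter in 1 further dexamethasone pair. In the 10 libraries of the 5 pairs, Mpo ranged from 12.17 to 14.55 log2(CPM + 1), while the erythroid regulator genes Gata1 and Klf1 had medians of 1.18 and 1.68 against 8.93 and 9.39 in the 36 deeper libraries of pairs without a myeloid-like daughter. The 10 were not alike in this: cell 2 of dexamethasone pair 10 held both, Gata1 at 7.47 and Klf1 at 6.84, where the lowest Gata1 of the 36 was 6.90, and Hba-a1 reached 7.44 in its sister. Of the 36, 1 is cell 1 of untreated pair 12, whose sister had a myeloid score of 6.47 and a late erythroid score of 3.65 but, at 11791 counts, was too shallow to be classed. In the pair with 1 such daughter Mpo was at 12.46 and 3.06, the first in the library with the fewest counts of the 48 (210383). That library also held Klf1 at 12.89 and Hba-a1 at 9.23, with Gata1 and Prtn3 at 3.93 each and Spi1 at 2.52. Its class is therefore uncertain, though the pair was counted and left out as one with a myeloid-like daughter. Mpo, Gata1 and Klf1 enter the scores that define the rule. Pairs with a myeloid-like daughter numbered 2 of 10 untreated and 4 of 13 dexamethasone pairs (Fisher's exact p = 0.66).

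**Figure D4:**
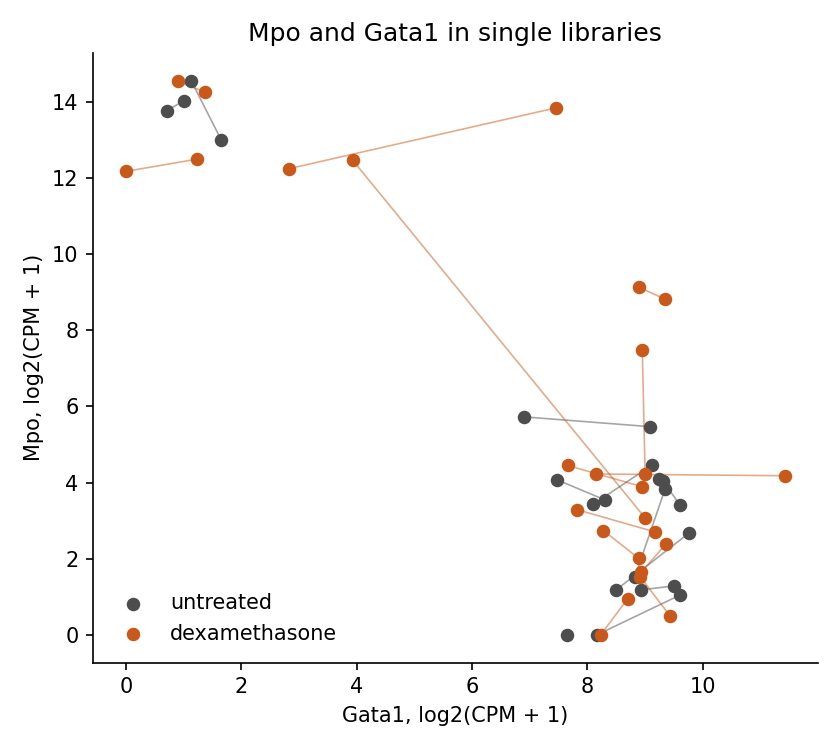
Mpo against Gata1 in libraries with at least 100000 counts, both as log2(CPM + 1). Lines join the 2 daughters of a founder; the 10 libraries of 5 pairs sit between 12.17 and 14.55 for Mpo, the 36 libraries of pairs without a myeloid-like daughter lie at or below 9.12, and 1 pair joins a library at 12.46 to one at 3.06.

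The next comparison asked where cells lay between early progenitor and later erythroid expression. The erythroid progression score of a pair was 0.01 ± 2.39 with and 0.90 ± 1.80 without dexamethasone (SD, n = 13 each), a difference of -0.89 (95% bootstrap interval -2.50 to 0.63, permutation p = 0.298). The difference was -2.15 in plate columns 1 to 4 (n = 8 pairs each, exact permutation p = 0.0516) and 1.13 in columns 5 to 7 (n = 5 pairs each, exact permutation p = 0.389). Without the 3 shallow pairs the contrast of the 2 column sets gave permutation p = 0.0316, or 0.288 adjusted over 37 scores and genes. Without myeloid-like pairs as well, the difference in columns 1 to 4 was -1.045 (exact permutation p = 0.149). The difference between daughters averaged 0.94 ± 0.47 untreated (SD, n = 12) and 0.79 ± 0.72 with dexamethasone (SD, n = 13; permutation p = 0.545). In pairs with 2 deep libraries the intraclass correlation of the score was 0.911 untreated and 0.908 with dexamethasone, and without myeloid-like pairs it was 0.776 and 0.821.

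**Figure D5:**
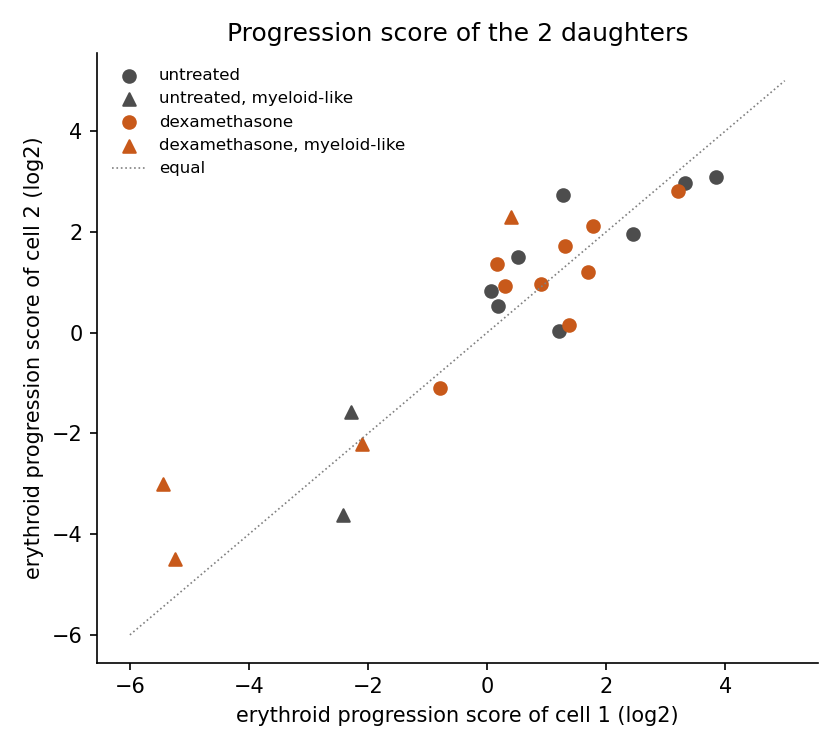
Erythroid progression score of cell 1 against cell 2 of each pair with at least 100000 counts in both libraries, as the mean log2(CPM + 1) of late erythroid minus early progenitor genes. Triangles are pairs with a myeloid-like daughter, the dotted line marks equal scores, and the intraclass correlation is 0.911 untreated and 0.908 with dexamethasone.

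The difference between daughters was then compared for 21 list scores. With dexamethasone 0 of 21 changed (0 with an unadjusted p under 0.05; smallest permutation p = 0.107, 0.911 adjusted, for CDK inhibitors and cyclins). The G2/M score differed between daughters by 1.00 ± 1.04 untreated (SD, n = 12) and 0.62 ± 0.36 with dexamethasone (SD, n = 13), and the glycolysis score by 0.62 ± 0.66 and 0.84 ± 0.63. As a negative control, cell 1 was compared with cell 2 of the pairs. The edgeR test called 0 of 8080 genes (277 with an unadjusted p under 0.05), and limma called 0 (443 with an unadjusted p under 0.05).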

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

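Leaving out shallow pairs or pairs with a myeloid-like daughter, leaving out each pair for the gene lists, the filter of 10 counts in 5 pairs, terms within a plate column, the permutation test of the 15 genes, the column sets for those genes and for the progression score, and all counts over splits and re-pairings were chosen after the data had been seen; the other alternatives were planned before the data were examined. Where a value below differs from the report, the cause was not tested unless it is named.

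For dexamethasone, edgeR called 0 genes, and 24 of 27 alternatives and each of the 26 fits without 1 pair gave 0 as well. DESeq2 called 2, the filter of 10 counts in 5 pairs 6 (Ankrd6, Ccdc28a, Dusp1, Hdac8, Hist1h1e and Naglu; 0 without shallow pairs) and no filter 2180. Of those 2180 genes 1897 had a count in fewer than 5 pairs. All 100 random splits of the 26 pairs gave at least 0 genes (highest other 1), which holds for any split and says nothing about chance. Tsc22d3 kept its call in 4 of 15 alternatives, each a permutation test adjusted over the list alone. In the other 11 it was higher but not called, at adjusted permutation p = 0.493 in columns 5 to 7, 0.476 there without shallow pairs, and at adjusted p = 0.459 to 1.00 over all genes in edgeR and limma. In counts simulated with the spread between these pairs, 0% of the 2-fold changes were recovered, so changes of that size would mostly be missed. Depth was not varied in that simulation.

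The 4 called lists became 0 without shallow pairs, 3 with the plate columns added to that fit (glycolysis, G1/S and mitochondrially encoded genes, adjusted p = 0.0269 each by camera), 0 with the wider filter without shallow pairs, 2 without myeloid-like pairs as well (glucocorticoid response and G1/S, adjusted p = 0.0344 each by camera, 0.293 each with an estimated correlation and 0.479 each by fry), 0 with an estimated correlation and 1 with fry. Leaving out 1 pair gave 1 to 9 lists: 1 without untreated pair 12, 2 without dexamethasone pair 6, 7 without untreated pair 11, 8 without untreated pair 9, 10 or 13, and 9 without dexamethasone pair 12. The late erythroid call was lost without untreated pair 1, 4, 6, 8 or 12 or dexamethasone pair 6, 7, 8 or 10 (adjusted p = 0.0621 to 0.291), and with detected genes as covariate (0.0530), and it held in 3 of 11 other alternatives. G2/M genes lost theirs without untreated pair 12 or dexamethasone pair 6 or 7 (0.0557 to 0.163), and G1/S genes without untreated pair 12 (0.0557). Heme synthesis genes passed with RLE scaling (0.0488), with the wider filter (0.0201) and without untreated pair 5, 9, 10, 11 or 13 or dexamethasone pair 1, 3, 9, 12 or 13 (0.00260 at the lowest). G2/M genes turned upward without shallow and myeloid-like pairs (adjusted p = 0.688 by camera). In 37 of 100 splits as many lists were called (highest other 12), so chance cannot be excluded.

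The similarity of daughters kept its direction and its side of the threshold in all 12 alternatives for each treatment. The difference in divergence was -0.0048 after subtracting the mean over non-daughter cells and -0.00023 without cell cycle genes. Genes shared by daughters numbered 516 by limma, 37 in untreated and 138 in dexamethasone cells alone (fewer pairs), 66 within a plate column, 90 there without shallow pairs, 270 by edgeR and 650 by limma without shallow pairs, and 34 by edgeR and 227 by limma without shallow and myeloid-like pairs. Of 100 re-pairings tested with limma, 1, the real one, gave as many genes (650, highest other 38). Chance can therefore be excluded for the limma count without shallow pairs; those re-pairings crossed plate columns and do not cover the 262 calls of edgeR. For cell 1 against cell 2 all 100 swaps gave at least the 0 genes called (limma, highest other 4), which holds for any swap and says nothing about chance. Its 3 alternatives called 0 genes. None of the 5 alternatives called a difference in list scores between daughters.

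The progression score difference was 1.13 in plate columns 5 to 7, 1.61 there without shallow pairs and 0.75 without shallow and myeloid-like pairs. Its difference between daughters was 0.027 with thinned counts and 0.13 in columns 1 to 4 without shallow pairs. In columns 5 to 7 Per1 was at -0.47 by permutation and -0.44 without shallow pairs. Fkbp5 was at 0.026 there and at -0.26 without shallow untreated pair 12.

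Pair numbers do not pair the treatments: same-numbered pairs correlated from -0.12 to 0.18, and 1 of 13 correlated best with its own number. With the pair number as a block edgeR called 0 genes (132 with an unadjusted p under 0.05) and camera 5 lists, and the progression difference was -0.892 (permutation p = 0.35). In that fit Kel was at -1.43, Nr3c1 at 0.053, Klf1 at -0.14, Hba-a1 at -0.46 and Alas1 at 0.26.

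Of the genes named for dexamethasone, 19 changed the sign of their log2 fold change in at least 1 alternative, and none of those genes had been called. With DESeq2 Kel was at -1.46, Mthfd2 at 0.019, Alas1 at 1.19 and Tpx2 at 0.24. By limma on pair means Kel was at -0.62, Nr3c1 at 0.23, Klf1 at -0.35, Hba-a1 at -0.56 and Alas1 at 1.01. By limma on single cells Kel was at -0.58, Nr3c1 at 0.13, Klf1 at -0.33, Hba-a1 at -0.49, Alas1 at 1.13 and Tpx2 at 0.0088. With cell 1 alone Gata1 was at -0.62. With cell 2 alone Mthfd2 was at 0.59, Map2k2 at 0.90, Kit at -0.14, Tpx2 at 0.28 and Tpi1 at -0.86. With the plate row as covariate Nr3c1 was at 0.080, Gata2 at -0.39 and Alas1 at 0.83. With the plate columns as covariate Klf1 was at -0.054, Hba-a1 at -0.067 and Alas1 at 0.30. In columns 1 to 4 Kel was at -2.04, Nr3c1 at 0.40, Gata1 at -0.43, Klf1 at -0.49, Hba-a1 at -1.67, Alas1 at 1.75 and Tacc3 at 0.040. In columns 5 to 7 Mthfd2 was at 0.65, Zfp36l2 at -1.37, Kit at -2.17, Epor at 0.36, Hbb-bt at 0.98, Etv6 at -0.40 and Tpx2 at 1.27. Without pairs with a cell under 2000 detected genes, which leaves out untreated pair 4 alone, Mthfd2 was at 0.0059 and Tpx2 at 0.28. With the log of detected genes as covariate Map2k2 was at 0.11, Zfp36l2 at -0.034, Kit at -0.36, Gata2 at -0.27 and Tpx2 at 0.18.

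Without shallow pairs Mthfd2 was at 0.15, Map2k2 at 0.16, Gata2 at -0.10 and Tpx2 at 0.20, and with the wider filter Mthfd2 was at 0.22, Map2k2 at 0.18, Gata2 at -0.084 and Tpx2 at 0.25. By limma without shallow pairs, with either filter, Kel was at -0.86, Mthfd2 at 0.18, Zfp36l2 at -0.40, Nr3c1 at 0.059, Gata1 at -0.066, Klf1 at -0.088, Hba-a1 at -0.22, Alas1 at 1.58 and Gapdh at -0.088. With the plate columns added Kel was at -0.85, Mthfd2 at 0.16, Zfp36l2 at -0.41, Nr3c1 at 0.032, Gata1 at -0.081, Klf1 at -0.092, Hba-a1 at -0.22, Alas1 at 1.59 and Gapdh at -0.091. By limma without myeloid-like pairs as well Kel was at -2.38, Zfp36l2 at -0.74, Nr3c1 at 0.85, Kit at -0.24, Klf1 at -0.13, Hba-a1 at -0.98, Alas1 at 1.03, Wdr76 at 0.20, Tpx2 at 0.30, Tacc3 at 0.54 and Gapdh at -0.051. By edgeR without those pairs Kel was at -1.67, Map2k2 at 0.26, Nr3c1 at 0.92, Kit at -0.093, Epor at 0.018, Alas1 at 0.73, Wdr76 at 0.10, Tpx2 at 0.38 and Tacc3 at 0.13. With the plate columns added to that fit Kel was at -1.64, Map2k2 at 0.33, Zfp36l2 at -0.049, Nr3c1 at 0.88, Kit at -0.12, Klf1 at -0.090, Hba-a1 at -0.65, Alas1 at 0.74, Wdr76 at 0.062, Tpx2 at 0.38, Tacc3 at 0.098 and Gapdh at -0.0035.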

Other observations

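The tests of a library batch, of a mix of cell types and of Tsc22d3 in daughters had their bounds set before the values were seen. The other tests in this part, the myeloid-like rule and the comparison of plate columns were chosen after the data had been seen, and the bound for low Mpo counts was narrowed after its value was known.

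Between columns 5 to 7 and columns 1 to 4, with the treatment in the model and without pairs with a shallow library, edgeR called 86 of 7190 genes, 74 higher and 12 lower in columns 5 to 7. Higher were Eif6 of ribosome assembly (1.32), Ranbp1 of nuclear transport (0.92) and Uqcrq, a subunit of respiratory complex III (1.33), all as log2 fold changes. Lower were the mitochondrially encoded mt-Rnr2 (-1.79), mt-Co1 (-1.41), mt-Nd5 (-1.30) and mt-Nd1 (-0.75), and the helicase gene Ddx5 (-0.85). These genes were singled out after their values were seen. No gene of 6429 showed an interaction of dexamethasone with the plate columns in edgeR (all pairs; 360 with an unadjusted p under 0.05; no other tool was run).

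For the plate columns, 1 of 100 splits of the pairs within a treatment, the real one, gave as many genes (86, highest other 34). The splits moved single pairs, whereas the real sets keep all pairs of a plate column together. An effect of any single column could therefore raise the real count above the others. The comparison was also chosen after the data had been seen, so the splits cannot exclude chance between columns. A library batch is a candidate explanation: the difference went the same way in untreated and dexamethasone pairs more than in other splits (correlation across genes 0.251, 1000 splits, one-sided permutation p = 0.012, highest other 0.334), and genes are not independent replicates. A different mix of cell types may contribute: 15 genes were called without pairs with a myeloid-like daughter, and 11 of the 86, or 12.8%, were among them. Leaving out as many random pairs 20 times kept a median of 6.5 of the 86 (range 0 to 29), so the lost calls can come from fewer pairs alone and the mix stays open. No other biological explanation was tested, since the labels give the columns no other difference.

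In 5 pairs both daughters carried granulocyte transcripts, against 1.16 pairs expected from re-pairing within a treatment (permutation p = 9e-05) and 2.48 within a plate column as well (permutation p = 0.0075), and founders of another lineage in the sort are a candidate explanation, although the labels' protocol depleted granulocytes before the sort. Mpo, Prtn3, Spi1 and Cd34 had medians of 13.80, 10.37, 8.32 and 9.64 log2(CPM + 1) in the 10 libraries, and Cd34 is also in the early progenitor list. Other markers were uneven there: Ctsg ranged from 2.01 to 13.06, Lyz2 from 0 to 12.34 and Elane from 0 to 11.98, with an Elane median of 0.92. In the daughters of untreated pair 9 Elane was at 11.98 and 1.155, and Lyz2 at 0.84 and 12.34. Reads misassigned from other libraries would add transcripts and remove none. The 10 libraries are also the pairs with both daughters high in Mpo alone (at least 12.17 against at most 9.12 in the others). Their median adult globin score differed from that of the others by -1.42 SD. For the 10 as a set this argues against misassigned reads as the whole cause. The ranges overlapped, with the highest of the 10 at 5.22 and the others at a median of 5.17 and a lowest of 0.13. In dexamethasone pair 10 Hba-a1 was at 7.44 and 6.24 and Kel at 14.43 and 16.02, so the argument does not cover that pair. Low Mpo counts in the other libraries may come from misassigned reads: 5 pairs sharing a plate column with a high-Mpo pair had log2 counts of 6.64 ± 1.66 and 12 other pairs 4.95 ± 2.41 (SD, exact permutation p = 0.177), which leaves it open. Whether these founders were multipotent or already granulocytic was not tested, and 3 libraries lay within 1 log2 unit of the boundary of the rule.

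Dexamethasone founders may differ in their response. The variance of the glucocorticoid list score between pairs was 3.33 times that of untreated pairs (15 genes, one-sided permutation p = 0.0191, 0.209 adjusted over 21 lists), and the ratio was 10.3 in plate columns 1 to 4 and 0.715 in columns 5 to 7. Other lists spread as much, with ratios of 4.10 for interferon and 3.45 for p53 genes, and 16.8 for ATF4 targets in columns 1 to 4, so chance, the plate columns and the founders all remain as explanations. If both daughters shared the response, Tsc22d3 would differ less between daughters than between re-paired cells; the mean differences were 2.94 ± 2.89 (SD, n = 13 pairs) and 3.49 (one-sided permutation p = 0.218). The bound set beforehand counted a p of 0.05 or more against sharing, but it was too weak to do so, since the difference lay in the predicted direction.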
